A study of Mus musculus with 16 samples.

How the data were processed

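The series profiled messenger RNA of cultured mouse bone marrow-derived cells by RNA sequencing. The series title calls the cells mast cells, while the cell type label of each sample expands the same abbreviation as mononuclear cells. The report follows the title and gives the mast cell transcripts in every group. The 16 libraries form 4 groups of 4: wild type untreated, wild type with IL-33, Nbeal2-/- untreated and Nbeal2-/- with IL-33. Groups were taken from the sample labels. The dose and duration of IL-33, the age of the cultures and the part of Nbeal2 that was deleted are not given in the sources used here. Nothing in the labels says whether replicates came from separate animals, so p-values measure only the spread between these samples.

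Per the labels' protocols, total RNA was isolated with Qiazol and made into strand-specific poly(A) libraries, and the mice had a C57BL/6 background. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.20.0.422 and counted per gene with featureCounts 1.6.5 on genome build GRCm38. The aligner, the annotation release and the strand setting of the counting are not given in the sources used here. Overlapping or antisense genes, and families of near-identical genes, are therefore reported as uncertain. The mast cell protease genes, the tryptases, the globins and the processed pseudogene Tma7-ps belong to such families.

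The authors deposited a table of raw counts per gene with 1 column per library, and the same libraries in RPM and in RPKM. The deposited RPM values equalled the counts scaled by each column total, with a largest difference of 4.91e-11. The deposited RPKM values were the RPM values divided by a fixed length per gene and entered no test. The count table holds 55487 genes, of which 29066 had no count in any library, and no blank gene names. Of the gene identifiers, 55141 matched the GENCODE M21 annotation, which supplied positions on GRCm38. It matched 15448 of the genes tested. Library totals ran from 36405209 to 57694499 counts, so a gene at 1 CPM of the library total rests on at least 36.4 counts in each library. Between libraries of a group the counts differed well beyond sampling noise, with a smallest chi-square per degree of freedom of 5.32 over genes with a total over 20, so each library counted as 1 sample.

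Tests used the deposited counts in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr over the 4 groups, which left 15470, and scaled by TMM. A model of 4 group means was fitted to all 16 libraries with robust quasi-likelihood dispersion. Its common biological coefficient of variation was 9.56%. From that fit 5 contrasts were taken: IL-33 against untreated in each genotype, Nbeal2-/- against wild type in each condition, and the difference of the IL-33 response between the genotypes. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. Counts of genes with a log2 fold change over 1 in size are given beside the full counts. Unless another test is named, an adjusted p of a gene comes from this edgeR quasi-likelihood test. Standard errors (SE) are on the log2 scale and were computed from the fold change and its F statistic. Levels are CPM with TMM factors, as mean ± SD over 4 libraries.

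Before the data were examined, the groups, tests, alternatives, gene lists and the rule for named genes were fixed. Of 26 lists, 22 had at least 5 tested members and were tested: mast cell identity, mast cell granule content, cytokines and growth factors, chemokines, NF-kB subunits and feedback, MAP kinase early and feedback genes, IL-33 receptor pathway, BEACH proteins and Nbeal2 partners, granule exocytosis, lysosome, eicosanoid synthesis, cell cycle, interferon response, unfolded protein and integrated stress response, cholesterol synthesis, glycolysis and hypoxia, and markers of megakaryocytes and platelets, monocytes and macrophages, basophils, lymphocytes and dendritic cells, progenitors and erythroid cells. Neutrophil and eosinophil markers had too few tested members, and sex-linked and substrain genes served as checks. Some genes sit on more than 1 list. Each list was compared with all other genes by camera of limma 3.58.1 with its preset correlation of 0.01, adjusted over the 22 lists. Camera with an estimated correlation was the main alternative. Genes named in the text come from this rule: Nbeal2, the 5 largest rises and 5 largest falls per contrast, and up to 4 called members of each list with the smallest p, or up to 2 where none was called. Some genes that the rule names are not reported here. The 5 had to pass the threshold, reach a mean of 5 CPM in the higher group and show no overlap between the libraries compared, leaving out predicted genes and genes named only by an identifier. For the difference of responses, the responses of the cultures had to show no overlap. Where a group held no count, the fold is a lower bound against 3 counts over the group. Where it held 1 to 3, the ratio has an exact binomial 95% counting interval. The sources used here name no molecular identifiers, so these intervals and floors cover counting error only.

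Labels give both conditions of a genotype the replicate numbers 1 to 4. Deviations from the group means over 10582 genes with a log2 CPM over 2 correlated between the untreated and the IL-33 library of each number. The correlations were 0.32, 0.55, 0.71 and 0.68 in wild type and 0.42, 0.48, 0.36 and 0.25 in Nbeal2-/-, across genes that are not independent. All 8 were positive, and 7 of the 8 numbers were each other's best match. The exception was wild-type IL-33 library 1, which correlated more with untreated library 2 (0.378) than with untreated library 1. Each number within a genotype is called a culture on this evidence from the data, giving 8 cultures, with the match of wild-type number 1 the least certain. Across genotypes number 1 matched, at 0.75 without and 0.52 with IL-33, and numbers 2 to 4 did not. The size of the IL-33 response was compared between 4 and 4 cultures by an exact two-sided permutation test, on mean log2 CPM changes with a prior count of 2.

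Alternatives were RLE and upper-quartile factors, no filter, a filter of 1 CPM in at least 4 libraries, DESeq2 1.42.0, limma-voom, limma on log2(RPM + 1), a fit on only the groups compared, a block for the replicate number, fry, and leaving out each library. Leaving out the 4 libraries numbered 1, also in the fits on 2 groups, a covariate of Y-linked counts, with or without its own slope with IL-33, and the BEACH list without Nbeal2 were chosen after seeing the data. The pipeline was tested on simulated counts with 100 genes changed by 2-fold and 100 by 1.5-fold. For IL-33 in wild type it recovered 83 and 63 of them with 10 false calls, and for IL-33 in Nbeal2-/- 88 and 67 with 7, over 15291 genes. For the genotypes with IL-33 it recovered 84 and 63 with 5 false calls and for the difference of responses 79 and 56 with 6, over 15291 genes. For the genotypes without IL-33 it recovered 92 and 70 with 12 false calls over 15293 genes. DESeq2 made 18 to 26 false calls in the 5 comparisons, 10% to 13.4% of its calls, against 3.11% to 6.49% with edgeR. Counts were simulated in a single draw per changed group, from dispersions estimated by edgeR, with most genes unchanged.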

Results

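Polyadenylated RNA was sequenced from mast cells grown from the bone marrow of wild-type (WT) mice and of mice lacking Nbeal2. Nbeal2 encodes a BEACH-domain protein that platelets need to form alpha granules. Cultures were left untreated or received IL-33, an alarmin cytokine that mast cells sense through the receptor chain encoded by Il1rl1 and that activates NF-kB. Each of the 4 groups held 4 libraries. Library totals ran from 39080187 to 54894255 counts in untreated WT, from 40050802 to 57694499 in WT with IL-33, from 44109341 to 52066492 in untreated Nbeal2-/- and from 36405209 to 51419415 in Nbeal2-/- with IL-33.

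The mast cell transcripts Kit and Il1rl1 were abundant in every group. Not all genes on the mast cell identity list were, and Mrgprb1 had 0 counts over the untreated Nbeal2-/- libraries. The receptor tyrosine kinase gene Kit stood at 3855 ± 399 CPM in untreated WT, 1626 ± 105 in WT with IL-33, 2470 ± 294 in untreated Nbeal2-/- and 1143 ± 66.7 in Nbeal2-/- with IL-33 (SD, n = 4 each). Il1rl1 stood at 4370 ± 301, 4413 ± 126, 3491 ± 276 and 3844 ± 186 CPM in the same order. Of the neutrophil markers only Mmp8 passed the filter, at group means of 0.988 to 1.72 CPM, and it was not called in any contrast (adjusted p from 0.0848 to 0.951). Of the eosinophil markers Ccr3 and Il5ra passed it. Ccr3 stood at 18.6 ± 1.33, 8.86 ± 1.7, 7.35 ± 0.874 and 2.2 ± 0.436 CPM in the same order of groups and was called lower with IL-33 in each genotype and lower in Nbeal2-/- in each condition (adjusted p from 3.98e-08 to 2.31e-06). Il5ra lay between 0.486 and 1.18 CPM and was called once, for IL-33 in Nbeal2-/- (log2 fold change -1.31, adjusted p = 0.0283).

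In a principal component analysis the first component held 76.4% of the variance and separated the IL-33 from the untreated libraries. The second held 10.6% and separated the genotypes. The third held 4.80%, and the 4 libraries numbered 1 had its highest scores. Mitochondrial transcripts made up 3.04% ± 0.139 of the counts in untreated WT, 2.45% ± 0.0892 in WT with IL-33, 2.99% ± 0.121 in untreated Nbeal2-/- and 2.33% ± 0.102 in Nbeal2-/- with IL-33 (SD, n = 4 each).

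Sex-linked transcripts differed between cultures and were alike in the untreated and the IL-33 library of each. WT cultures 1 and 2 and Nbeal2-/- culture 1 had 160 to 201 CPM over the Y-linked genes and at most 0.198 CPM of Xist, which is transcribed from the inactive X chromosome. WT culture 4 had 2.31 and 5.41 CPM of Y-linked transcripts with Xist at 1851 and 1206 CPM. WT culture 3 and Nbeal2-/- culture 2 had mostly Xist, at 936 to 1317 CPM, with Y-linked sums of 18.7 to 23.5 CPM. Nbeal2-/- cultures 3 and 4 had both, with Y-linked sums of 119 to 167 CPM and Xist at 131 to 388 CPM. Of the substrain genes, Nnt stood at 0.384 to 1.02 CPM of the library total in all 16 libraries, Wdfy1 at 24.6 to 33, Entpd4 at 41.1 to 64.1 and Ide at 156 to 309.

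Nbeal2 (ENSMUSG00000056724) lies on chromosome 9 at 110624789 to 110654161 of GRCm38, on the minus strand. The libraries of WT cultures 1 to 4 held 224, 448, 413 and 423 CPM without IL-33 and 183, 253, 249 and 258 CPM with it. Those of Nbeal2-/- cultures 1 to 4 held 85.0, 103, 95.7 and 87.2 CPM without IL-33 and 76.9, 64.3, 68.9 and 72.8 CPM with it. Every Nbeal2-/- library lay below every WT library. Nbeal2-/- cells kept transcript counts of the gene, at means of 92.6 ± 8.13 and 70.7 ± 5.38 CPM (SD, n = 4 each). Levels fell by 2.02 on the log2 scale without IL-33 (SE 0.17, adjusted p = 1e-06) and by 1.74 with it (SE 0.17, adjusted p = 1.05e-05). WT culture 1 was the lowest of the WT cultures in both conditions. Gene counts cannot say which part of the transcript remained.

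**Figure D1:**
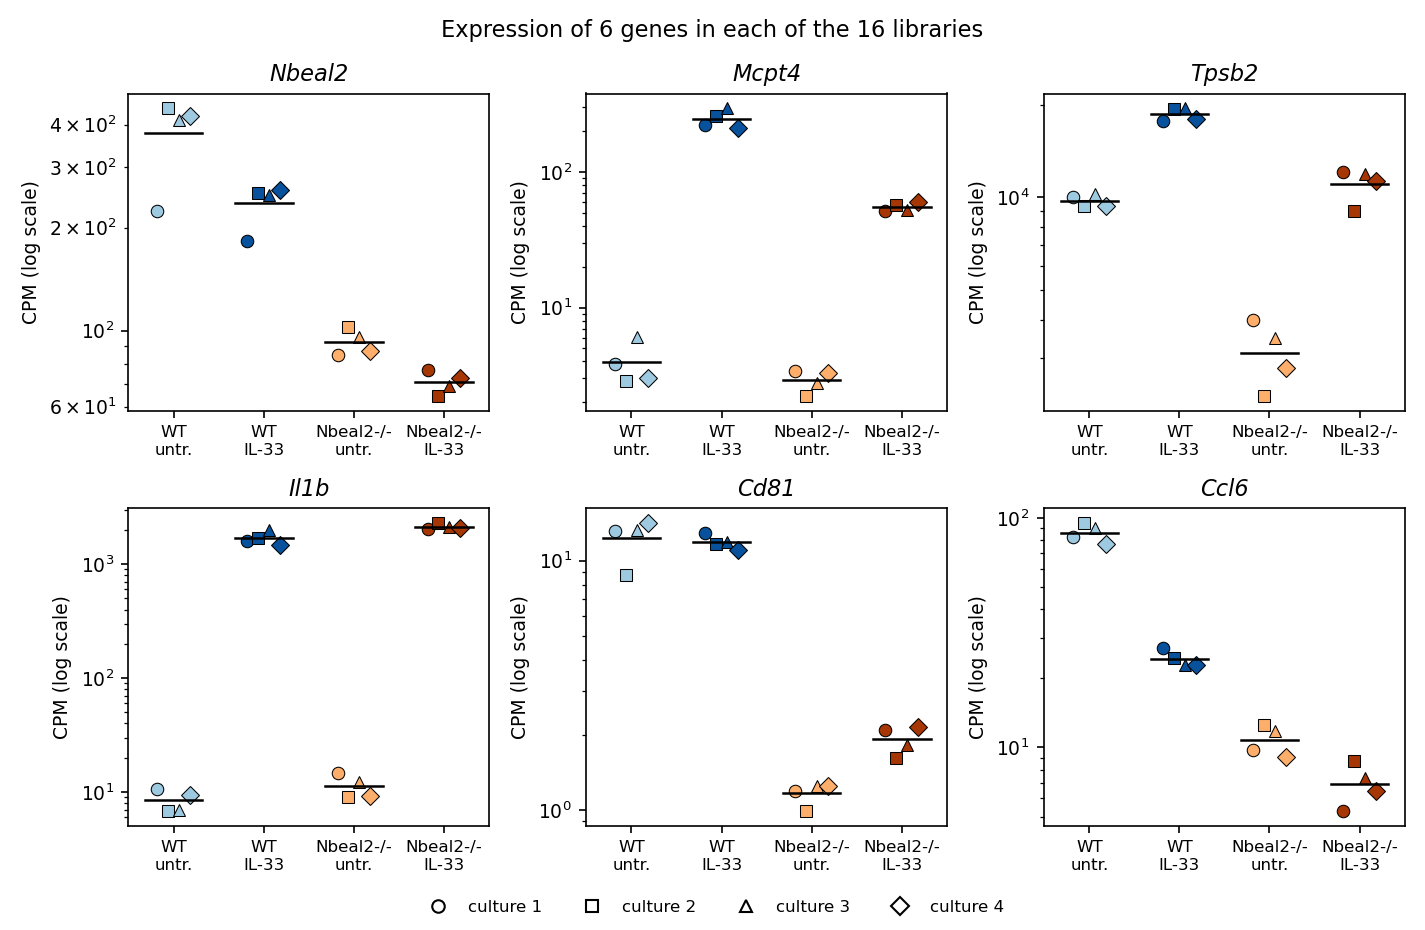
Levels of Nbeal2, Mcpt4, Tpsb2, Il1b, Cd81 and Ccl6 in each library, in CPM on a log axis, by group. Marker shapes give the culture number and bars the mean of 4 libraries, and Nbeal2 in WT culture 1 lies at 224 and 183 CPM, below the other WT cultures.

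The first question was what IL-33 did in WT mast cells. It took several cytokine and chemokine genes from near silence to high levels. Il9, which encodes a mast cell growth factor (chromosome 13, 56479277 to 56482246), rose from 1 count over the 4 untreated libraries to 113 ± 36.2 CPM (SD, n = 4), a ratio of 20879 (95% counting interval 3747 to 824701). Il1b, an inflammatory cytokine gene (chromosome 2, 129364570 to 129371139), rose 201-fold, from 8.42 ± 1.88 to 1702 ± 223 CPM (log2 fold change 7.65, SE 0.20, adjusted p = 1.1e-14). Csf2, the gene of GM-CSF, had 3 counts over the untreated libraries and rose to 27.9 ± 3.85 CPM, a ratio of 1766 (604 to 8569). Kit fell 2.37-fold (log2 fold change -1.25, SE 0.09, adjusted p = 1.23e-09).

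Other large rises were Ccl22, a chemokine gene, at least 1597-fold higher, Ces2c, at least 467-fold higher, and Ccdc184, at least 333-fold higher. Here and below, the largest changes are those among called genes with a mean of at least 5 CPM in the higher group and no overlap between the libraries compared, leaving out predicted genes. The largest falls were Fat3 (log2 fold change -5.98, SE 0.40, adjusted p = 2.45e-09), Cd24a, from 27.0 ± 10.8 to 0.428 ± 0.133 CPM, Cyp4a12b, from 140 ± 31.5 to 3.78 ± 0.793 CPM, the transglutaminase gene Tgm2, from 69.3 ± 3.91 to 2.01 ± 0.662 CPM, and Ngfr, which fell 31.4-fold.

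Genes of NF-kB subunits and their feedback regulators moved as a block in WT cells. Of 23 tested, 22 rose and 1 did not pass (22 adjusted over the list alone), with a median log2 fold change of 1.45. Nfkb2 rose 10.4-fold, from 42.2 ± 1.4 to 438 ± 17.8 CPM, Zc3h12a 9.4-fold, and Nfkbiz had a log2 fold change of 3.33 (camera adjusted p = 3.32e-61 for the list). Of 13 chemokine genes 11 rose and 2 fell (13 called adjusted over the list alone), with Ccl1 up 157-fold, Cxcl16 53.6-fold, and Ccl3 at a log2 fold change of 3.70 (camera adjusted p = 1.49e-13). Both medians were the same with Ccl22 and Bcl2a1d, which had no count in untreated WT, set to their lower bounds. Of 19 cytokine and growth factor genes 10 rose, 5 fell and 4 did not pass (16 called adjusted over the list alone), with Ebi3 up 36.5-fold and Tnf 7.62-fold (camera adjusted p = 2e-10).

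Granule content genes rose too, led by proteases of near-identical families whose reads may be shared. Of 21 tested 16 rose, 4 fell and 1 did not pass (20 called adjusted over the list alone, camera adjusted p = 2.76e-12). Mcpt4, a chymase gene (chromosome 14, 56059629 to 56062313), rose 63.4-fold, from 3.95 ± 1.48 to 248 ± 38.2 CPM, and Mcpt1 and Mcpt2 rose from 0.0869 ± 0.0368 to 96.1 ± 13.2 and from 2.95 ± 0.0726 to 227 ± 42.3 CPM. The tryptase gene Tpsab1 rose 88.0-fold to 263 ± 21.2 CPM. Of 18 genes of the unfolded protein and integrated stress response 12 rose, 4 fell and 2 did not pass (16 called adjusted over the list alone, camera adjusted p = 1.21e-06, adjusted p = 0.0644 with an estimated correlation). The chaperone gene Hspa5 rose 2.41-fold and Dnajb9 2.18-fold. Of 20 cholesterol synthesis genes 18 rose and 2 did not pass (18 adjusted over the list alone, camera adjusted p = 5.37e-07, adjusted p = 0.341 with an estimated correlation), with Insig1 up 2.45-fold.

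Some markers of other cell types moved with IL-33 in WT cells. Of 6 megakaryocyte and platelet markers 5 fell and 1 rose (6 called adjusted over the list alone, camera adjusted p = 1.15e-05). Gp5, a platelet glycoprotein gene, fell 13.8-fold, from 86.1 ± 3.94 to 6.21 ± 0.745 CPM, and Gp1ba 3.91-fold. Of 7 lymphocyte and dendritic cell markers 6 rose and 1 fell (7 called adjusted over the list alone, camera adjusted p = 0.00587, adjusted p = 0.158 with an estimated correlation). The members with the smallest p were genes of MHC class II antigen presentation. Cd74, the invariant chain gene, rose from 1.2 ± 0.194 to 776 ± 136 CPM, H2-Aa 84.7-fold and H2-Ab1 16.5-fold.

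The other lists were not called by camera in WT. Mast cell identity genes went both ways, with 11 risen, 6 fallen and 4 not passing of 21 (18 called adjusted over the list alone, camera adjusted p = 0.877). Among them Slc18a2, the vesicular monoamine transporter gene, fell 2.27-fold and Mitf 1.74-fold. Cell cycle genes had 8 risen, 11 fallen and 6 not passing of 25 (21 called adjusted over the list alone, camera adjusted p = 0.907), with Mcm5 up from 214 ± 14.8 to 319 ± 13.5 CPM. The remaining counts of risen, fallen and tested genes were 9, 7 and 25 for MAP kinase early and feedback genes, 6, 8 and 21 for the IL-33 receptor pathway, 4, 3 and 16 for BEACH proteins, 7, 10 and 23 for granule exocytosis and 11, 9 and 26 for the lysosome. They were 3, 8 and 13 for eicosanoid synthesis, 5, 5 and 16 for the interferon response and 5, 2 and 20 for glycolysis and hypoxia. Markers of monocytes had 3, 3 and 9, of basophils 3, 4 and 10, of progenitors 3, 3 and 10 and of erythroid cells 3, 4 and 8. Adjusted over each list alone, the numbers called were 16, 14, 7, 18 and 20, then 11, 10 and 6, and for the markers 6, 8, 7 and 7. Camera adjusted p ran from 0.205 to 0.724 except for monocyte markers, at 0.822. Single members still changed strongly, with Ptgs2, the inducible cyclooxygenase gene, up 115-fold, Ltc4s down 3.27-fold, Gbp3 up 23.8-fold, Oasl2 down 7.16-fold, Marco up 28.4-fold and Cd69 up 8.83-fold. Median, mean and test differed in sign for BEACH proteins, lysosome, eicosanoid, cell cycle, interferon, monocyte, basophil and erythroid lists.

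In WT 8903 of 15470 genes were called, 4476 higher and 4427 lower, and 2024 of them changed over 2-fold (847 higher, 1177 lower). With limma on log2(RPM + 1) the share called higher was 38.1%, against 50.3% in the edgeR test. Of the 22 lists 8 were called, and 5 of those with an estimated correlation.

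The same question was asked of Nbeal2-/- cells. IL-33 raised Il9 from 1 count over the untreated libraries to 105 ± 13.6 CPM (SD, n = 4), a ratio of 20898 (3750 to 825475). Il1b rose 189-fold, from 11.3 ± 2.70 to 2134 ± 119 CPM (log2 fold change 7.56, SE 0.20, adjusted p = 1.05e-14). Tpsb2, an abundant tryptase gene (chromosome 17, 25366305 to 25369098), rose 3.53-fold, from 3136 ± 765 to 11083 ± 1423 CPM (adjusted p = 5.47e-09). Kit fell 2.16-fold (log2 fold change -1.11, SE 0.09, adjusted p = 5.55e-09). Nbeal2 itself had a log2 fold change of -0.39 with an adjusted p of 0.0644. With the culture as a block its value was -0.39 with an adjusted p of 0.00383, and with DESeq2 it was -0.39 with 0.0338.

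Other large rises were C1ql2, at least 519-fold higher, Csf2, with a ratio of 2623 (470 to 103633), and Ccl22, with a ratio of 1883 (337 to 74412). The largest falls were Nrgn (126-fold), Fat3 (33.3-fold), Mamdc2 (30.9-fold), Ngfr (21.4-fold) and Stard9 (19.4-fold).

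All 23 NF-kB genes rose in Nbeal2-/- (23 adjusted over the list alone, camera adjusted p = 1.47e-69), with Nfkb2 up 9.66-fold to 438 ± 14.2 CPM and Nfkbia 17.7-fold. Of 13 chemokine genes 10 rose, 2 fell and 1 did not pass (12 called adjusted over the list alone, camera adjusted p = 2.05e-16), with Cxcl16 up 168-fold, Ccl5 135-fold and Ccl1 72.1-fold. Of 19 cytokine genes 11 rose, 5 fell and 3 did not pass (16 called adjusted over the list alone, camera adjusted p = 2.92e-09), with Ebi3 up 24.3-fold and Tnf 5.36-fold. Of 21 granule content genes 16 rose, 3 fell and 2 did not pass (20 called adjusted over the list alone, camera adjusted p = 2e-11). Tpsab1 rose 412-fold to 114 ± 3.97 CPM, Mcpt1 767-fold, Mcpt2 16.2-fold to 69.5 ± 5.11 CPM and the granzyme gene Gzmc 23.9-fold. The untreated Nbeal2-/- libraries held only 0.0183 to 0.0642 CPM of Mcpt1, so its fold rests on few counts.

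Cell cycle genes fell with IL-33 in Nbeal2-/-. Of 25 tested 17 fell, 2 rose and 6 did not pass (21 called adjusted over the list alone, camera adjusted p = 1.91e-05, adjusted p = 0.341 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, fell 2.33-fold from 61.9 ± 1.86 to 26.6 ± 1.17 CPM, the cyclin gene Ccnb2 2.88-fold, the mitotic kinase gene Plk1 2.18-fold and the thymidine kinase gene Tk1 2.64-fold. Of 18 stress response genes 11 rose, 4 fell and 3 did not pass (15 called adjusted over the list alone, camera adjusted p = 1.77e-05, adjusted p = 0.0915 with an estimated correlation), with Hsp90b1 up 2.04-fold. Of 20 cholesterol synthesis genes 18 rose and 2 did not pass (20 adjusted over the list alone, camera adjusted p = 1.94e-09, adjusted p = 0.271 with an estimated correlation), with Insig1 up 2.61-fold. Of 20 glycolysis and hypoxia genes 13 rose, 1 fell and 6 did not pass (15 called adjusted over the list alone), with the hexokinase gene Hk2 up 2.02-fold and Ero1l 1.93-fold. Camera gave that list an adjusted p of 0.0629, and 0.000199 with the culture as a block.

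Of 6 megakaryocyte and platelet markers 4 fell, 1 rose and 1 did not pass (5 called adjusted over the list alone, camera adjusted p = 0.000267, adjusted p = 0.0593 with an estimated correlation), with Gp5 down 12.7-fold and Gp1ba 4.33-fold. Of 7 lymphocyte and dendritic cell markers 5 rose, 1 fell and 1 did not pass (6 called adjusted over the list alone, camera adjusted p = 0.00157, adjusted p = 0.0915 with an estimated correlation). Cd74 rose to 912 ± 117 CPM and H2-Aa 189-fold. Mast cell identity genes had 11 risen, 6 fallen and 4 not passing of 21 (18 called adjusted over the list alone, camera adjusted p = 0.552). The remaining counts of risen, fallen and tested genes were 6, 10 and 25 for MAP kinase genes, 7, 6 and 21 for the IL-33 receptor pathway, 8, 2 and 16 for BEACH proteins, 8, 10 and 23 for granule exocytosis and 12, 7 and 26 for the lysosome. They were 3, 6 and 13 for eicosanoid synthesis and 6, 3 and 16 for the interferon response. Markers of monocytes had 1, 2 and 9, of basophils 3, 4 and 10, of progenitors 5, 3 and 10 and of erythroid cells 3, 3 and 8. Adjusted over each list alone, the numbers called were 16, 15, 10, 18 and 21, then 9 and 9, and for the markers 3, 9, 8 and 6. Their camera adjusted p ran from 0.0820 to 0.982. Among their members the syntaxin gene Stx11 rose 3.33-fold and Irak3, a brake on IL-1 family signalling, 2.46-fold. Median, mean and test differed in sign for MAP kinase, BEACH, exocytosis, eicosanoid, interferon, monocyte, basophil and erythroid lists.

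In Nbeal2-/- 8524 of 15470 genes were called, 4209 higher and 4315 lower, and 1930 changed over 2-fold (892 higher, 1038 lower). With limma on log2(RPM + 1) the share called higher was 33.8%, against 49.4% in the edgeR test. Of the 22 lists 9 were called, and 4 of those with an estimated correlation. The responses of the genotypes shared 3425 of the genes called higher, where independent lists would share 1218, and 3425 of those called lower, where they would share 1235. Of the 6902 genes called in both, 52 moved in opposite directions. Log2 fold changes correlated across genes at r = 0.930, and genes are not independent replicates.

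**Figure D2:**
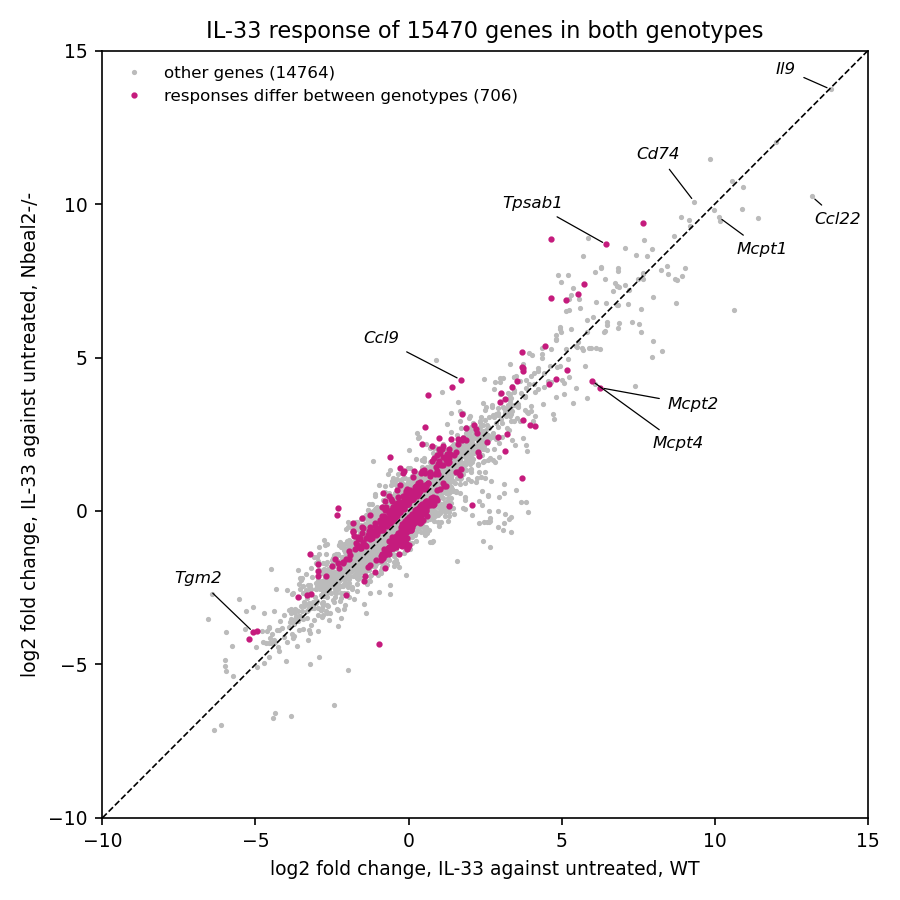
Log2 fold change with IL-33 in Nbeal2-/- against that in WT for the 15470 genes tested, 1 point per gene. Coloured points are the 706 genes whose response differed between the genotypes, and most points lie along the diagonal (r = 0.930 across genes).

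The next question was how untreated Nbeal2-/- cells differed from untreated WT cells. The chemokine genes Ccl9 and Ccl6 were among the 5 largest decreases. Cd81, a tetraspanin gene (chromosome 7, 143052739 to 143067934), was 10.6-fold lower, at 1.17 ± 0.121 against 12.3 ± 2.42 CPM (SD, n = 4 each, log2 fold change -3.41, SE 0.14, adjusted p = 7.14e-11). The neighbouring chemokine genes Ccl9 (chromosome 11, 83572919 to 83578636) and Ccl6 (83587882 to 83593087) were 9.13-fold and 7.98-fold lower, at 4.09 ± 1.36 against 37.6 ± 1.74 and 10.8 ± 1.65 against 86.3 ± 8.03 CPM (adjusted p = 1.81e-09 and 8.01e-11). Tpsb2 was 3.11-fold lower, at 3136 ± 765 against 9761 ± 461 CPM (adjusted p = 3.75e-07). Otop1, a proton channel gene (chromosome 5, 38275972 to 38304217), was 6.46-fold higher, at 28.8 ± 2.05 against 4.45 ± 0.437 CPM (log2 fold change 2.69, SE 0.10, adjusted p = 1.33e-11).

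The other largest increases were Plac8 (8.41-fold), Col6a2 (6.05-fold), Ctnna2 (4.37-fold) and Eomes, a T-box transcription factor gene (3.87-fold). Eomes lies within 10 Mb of Nbeal2 on chromosome 9, a region taken up below. The other largest decreases were Egln3, a gene induced by hypoxia, at 0.432 ± 0.256 against 6.05 ± 3.44 CPM, and the guanylate-binding protein gene Gbp9, 6.26-fold lower.

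Mast cell identity genes were lower in untreated Nbeal2-/- cells. Of 21 tested 12 fell, none rose and 9 did not pass (14 called adjusted over the list alone, camera adjusted p = 3.28e-06). Mrgprb2, the receptor gene for basic secretagogues, fell 4.69-fold to 9.02 ± 1.4 CPM, Kit 1.56-fold, and Mrgprb1 was at least 16.7-fold lower with no count in Nbeal2-/-. Of 21 granule content genes 9 fell, 3 rose and 9 did not pass (12 called adjusted over the list alone, camera adjusted p = 0.00618, adjusted p = 0.15 with an estimated correlation). Tpsab1 fell to 0.274 ± 0.08 from 2.95 ± 0.858 CPM and Gzmb 1.63-fold, while Serpinb1a rose 1.5-fold. Of 13 chemokine genes 6 fell, 3 rose and 4 did not pass (9 called adjusted over the list alone, camera adjusted p = 2.53e-09), with Ccl4 down 3.30-fold and Ccl3 3.23-fold. Of 23 granule exocytosis genes 8 fell and 15 did not pass (8 adjusted over the list alone, camera adjusted p = 0.0236, adjusted p = 0.162 with an estimated correlation). Rab27b, a GTPase gene of granule docking, fell by 0.32 on the log2 scale. Of 26 lysosome genes 15 fell, 2 rose and 9 did not pass (19 called adjusted over the list alone, camera adjusted p = 0.00102, adjusted p = 0.162 with an estimated correlation), with Psap down 1.45-fold and Hexa 1.17-fold.

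Of 16 BEACH proteins and Nbeal2 partners 4 fell, Nbeal2 and Lyst among them, and 12 did not pass (4 adjusted over the list alone, camera adjusted p = 0.0265, adjusted p = 0.455 with an estimated correlation). The list holds the deleted gene itself, and without Nbeal2, a choice made after seeing the data, 3 of 15 fell and the list was not called (camera adjusted p = 0.149). The call also ended without WT untreated library 2 (adjusted p = 0.0615) and without Nbeal2-/- untreated library 1 (adjusted p = 0.103). Of 20 glycolysis and hypoxia genes 15 fell and 5 did not pass (15 adjusted over the list alone, camera adjusted p = 3.28e-06, adjusted p = 0.384 with an estimated correlation), with Pfkp down 1.64-fold, from 423 ± 46.5 to 257 ± 22.4 CPM, and Hk2 1.61-fold. Of 6 megakaryocyte and platelet markers 3 fell and 3 did not pass (4 called adjusted over the list alone, camera adjusted p = 0.000672, adjusted p = 0.128 with an estimated correlation), with Vwf down 1.82-fold.

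Cell cycle genes were higher in untreated Nbeal2-/- cells. Of 25 tested 21 rose and 4 did not pass (23 adjusted over the list alone, camera adjusted p = 1.39e-08, adjusted p = 0.206 with an estimated correlation). Cdc20 rose 1.63-fold, from 38.0 ± 4.13 to 61.9 ± 1.86 CPM, Ccnb1 1.45-fold and Tyms 1.44-fold. Of 25 MAP kinase early and feedback genes 10 rose, 2 fell and 13 did not pass (12 called adjusted over the list alone, camera adjusted p = 0.00094, adjusted p = 0.206 with an estimated correlation), with Ier2 up 1.80-fold, Junb 1.76-fold and Myc 1.61-fold. Of 18 stress response genes 10 rose, 1 fell and 7 did not pass (11 called adjusted over the list alone, camera adjusted p = 0.000383, adjusted p = 0.162 with an estimated correlation), with the asparagine synthetase gene Asns up 1.56-fold. Of 8 erythroid markers 4 rose and 4 did not pass (5 adjusted over the list alone, camera adjusted p = 0.0109, adjusted p = 0.162 with an estimated correlation), with Car2 up 2.29-fold, from 13.7 ± 1.65 to 31.6 ± 5.55 CPM.

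The other 10 lists were not called by camera, with adjusted p from 0.0659 to 0.979. Counts of risen, fallen and tested genes were 8, 2 and 19 for cytokines and growth factors, 2, 8 and 23 for NF-kB genes, 3, 8 and 21 for the IL-33 receptor pathway, 2, 1 and 13 for eicosanoid synthesis, 3, 3 and 16 for the interferon response and 0, 3 and 20 for cholesterol synthesis. Markers of monocytes had 1, 3 and 9, of basophils 1, 5 and 10, of lymphocytes and dendritic cells 0, 1 and 7 and of progenitors 1, 2 and 10. Adjusted over each list alone, the numbers called were 11, 11, 12, 3, 8 and 1, and for the markers 4, 6, 0 and 3. Lif rose from 325 ± 27.9 to 569 ± 47.4 CPM, Il1rl1 fell by 0.32 on the log2 scale, Tnfaip3 fell 1.52-fold, and Adgre1, a macrophage marker gene, rose 3.00-fold from 8.42 ± 0.688 to 25.2 ± 5.01 CPM. The eosinophil marker Ccr3 fell 2.53-fold. Median, mean and test differed in sign for the eicosanoid and progenitor lists.

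Without IL-33, 5549 of 15470 genes were called between the genotypes, 2840 higher and 2709 lower in Nbeal2-/-. This count rests on a spread shared with the IL-33 libraries, which varied less, and it was lower when fitted on these 2 groups alone. Its ratio to the count with IL-33 was 3.21 in the shared fit and 1.23 in fits on the 2 groups alone. Over 2-fold there were 521, 139 higher and 382 lower. Of the 22 lists 12 were called, and 2 of those, mast cell identity and chemokines, with an estimated correlation.

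**Figure D3:**
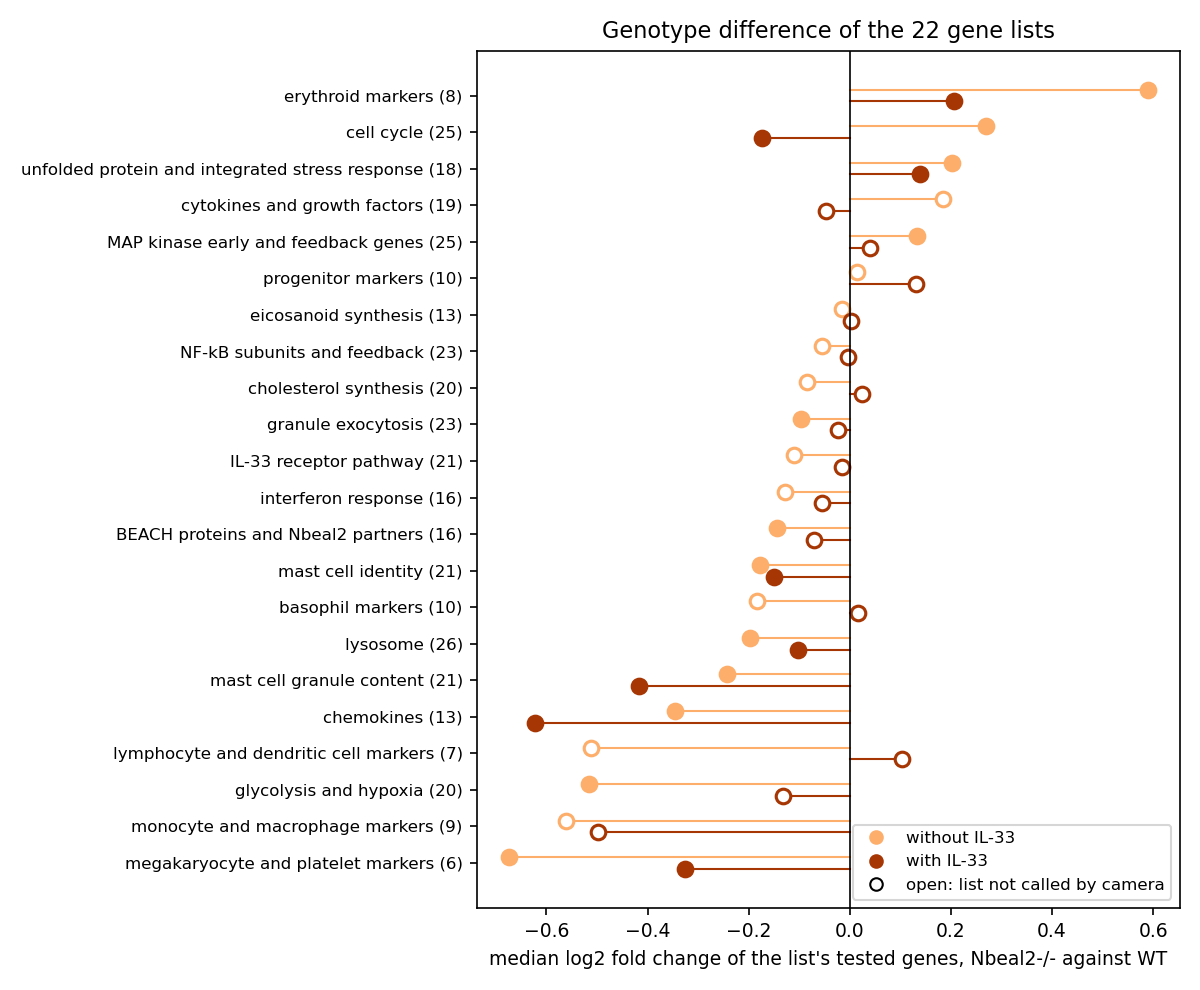
Median log2 fold change, Nbeal2-/- against WT, of the tested members of each of the 22 lists, without and with IL-33. Filled symbols mark lists called by camera and open symbols the others, and the cell cycle list lies at 0.27 without IL-33 and -0.17 with it.

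The genotypes were then compared in the presence of IL-33, where the mast cell protease genes Mcpt4, Mcpt1 and Mcpt2 were lower in Nbeal2-/- cells. Mcpt4 stood at 55.1 ± 4.05 CPM in Nbeal2-/- against 248 ± 38.2 in WT (SD, n = 4 each), 4.51-fold lower (log2 fold change -2.17, SE 0.16, adjusted p = 3.55e-07). Mcpt1 was 3.85-fold lower, and Mcpt2 3.26-fold lower, at 69.5 ± 5.11 against 227 ± 42.3 CPM (adjusted p = 4.66e-09 and 3.08e-08). Cd81 was 6.17-fold lower, at 1.92 ± 0.244 against 11.9 ± 0.792 CPM (adjusted p = 4.66e-09). Ephx2, the soluble epoxide hydrolase gene, was 3.46-fold higher, at 81.5 ± 12.1 against 23.7 ± 8.35 CPM (log2 fold change 1.79, SE 0.20, adjusted p = 2.84e-05).

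The other largest decreases were Tns1, at 4.04 ± 0.478 against 22.8 ± 6.85 CPM, Mrgprb2, at 4.35 ± 0.0649 against 24.1 ± 6.95 CPM, and Ccr3, 4.02-fold lower. The other largest increases were Zdhhc15 (3.75-fold), Tma7-ps (3.47-fold, adjusted p = 0.0448), Nradd (2.95-fold) and Ighm (2.84-fold). Tma7-ps is a processed pseudogene that can share reads with its parent gene. Nradd (chromosome 9, 110621135 to 110624452) ends 337 bp from Nbeal2 on the same strand and stood at 14.4 ± 0.116 against 4.83 ± 1.46 CPM.

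**Figure D4:**
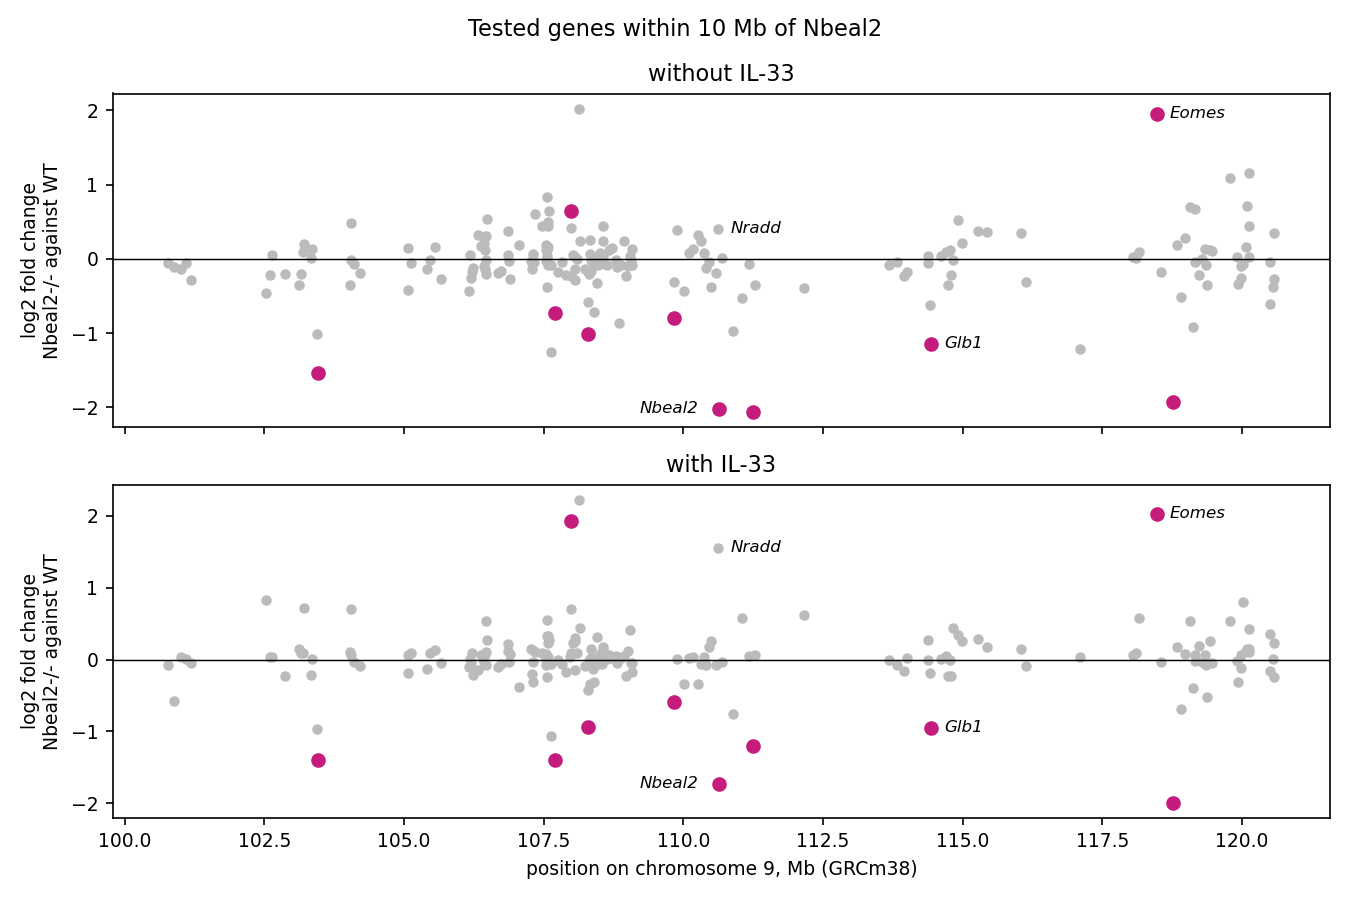
Log2 fold change, Nbeal2-/- against WT, of tested genes within 10 Mb of Nbeal2 on chromosome 9, by position, without and with IL-33. Coloured points are genes called in the same direction in both conditions with a change over 0.5 in size, with Nbeal2 at -2.02 and -1.74.

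Of 21 granule content genes 9 fell, 1 rose and 11 did not pass (12 called adjusted over the list alone, camera adjusted p = 7.72e-13), with Tpsab1 down 2.31-fold. Of 21 mast cell identity genes 8 fell and 13 did not pass (10 adjusted over the list alone, camera adjusted p = 4.34e-08), with Kit down 1.42-fold and Rab27b 1.23-fold. Of 13 chemokine genes 7 fell, 1 rose and 5 did not pass (10 called adjusted over the list alone, camera adjusted p = 1.11e-11), with Ccl24 down 6.04-fold, Ccl6 3.52-fold, Ccl22 2.66-fold and Ccl4 1.86-fold. Of 26 lysosome genes 7 fell, 1 rose and 18 did not pass (11 called adjusted over the list alone, camera adjusted p = 0.00964, adjusted p = 0.277 with an estimated correlation), with Psap down 1.29-fold and Lamp1 1.17-fold.

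Cell cycle genes were lower in Nbeal2-/- cells with IL-33, against their direction without it. Of 25 tested 12 fell and 13 did not pass (15 adjusted over the list alone, camera adjusted p = 5.13e-08, adjusted p = 0.277 with an estimated correlation), with Tk1 down 1.4-fold, Rrm2 1.23-fold and E2f1 1.21-fold. Of 18 stress response genes 5 rose and 13 did not pass (11 adjusted over the list alone, camera adjusted p = 0.00153, adjusted p = 0.277 with an estimated correlation), with Asns up 1.45-fold. Of 6 megakaryocyte and platelet markers 2 fell and 4 did not pass (3 adjusted over the list alone, camera adjusted p = 0.0305, adjusted p = 0.277 with an estimated correlation), with Gp5 down 1.45-fold. That call ended without WT IL-33 library 1 (adjusted p = 0.104), WT IL-33 library 4 (0.0519) or Nbeal2-/- IL-33 library 4 (0.0581). Of 8 erythroid markers 1 rose, Car2 by 2.17-fold, and 7 did not pass (1 adjusted over the list alone, camera adjusted p = 0.014, adjusted p = 0.277 with an estimated correlation).

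The other 14 lists were not called, with camera adjusted p from 0.0583 to 0.980. Counts of risen, fallen and tested genes were 2, 1 and 19 for cytokines and growth factors, 3, 1 and 23 for NF-kB genes, 5, 1 and 25 for MAP kinase genes, 3, 2 and 21 for the IL-33 receptor pathway, 1, 2 and 16 for BEACH proteins and 0, 2 and 23 for granule exocytosis. They were 2, 2 and 13 for eicosanoid synthesis, 1, 0 and 16 for the interferon response, 0, 1 and 20 for cholesterol synthesis and 0, 1 and 20 for glycolysis and hypoxia. Markers of monocytes had 1, 3 and 9, of basophils 1, 3 and 10, of lymphocytes and dendritic cells 0, 0 and 7 and of progenitors 1, 0 and 10. Adjusted over each list alone, the numbers called were 7, 5, 6, 5, 5 and 2, then 5, 1, 1 and 1, and for the markers 5, 4, 0 and 4. Csf2 fell 2.11-fold to 13.2 ± 2.42 CPM and Ptgs2 2.31-fold, Mcpt8, a basophil protease gene, fell 1.88-fold, Il6 rose 1.35-fold from 265 ± 37.0 to 358 ± 23.8 CPM, and Adgre1 rose 1.78-fold. Median, mean and test differed in sign for the cytokine, IL-33 receptor, eicosanoid, interferon, basophil and lymphocyte lists.

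With IL-33, 1730 of 15470 genes were called between the genotypes, 849 higher and 881 lower in Nbeal2-/-, and 268 changed over 2-fold (99 higher, 169 lower). Fitted on these 2 groups alone the count was 3113. Of the 22 lists 8 were called, and 3 of those, mast cell identity, granule content and chemokines, with an estimated correlation. The untreated and the IL-33 comparison draw on the same cultures and shared 537 genes called higher and 611 called lower, where independent lists would share 156 and 154. Of the 1224 genes called in both, 76 went in opposite directions. The fold changes correlated across genes at r = 0.576, and the differences of mean log2 CPM at r = 0.618. For the differences of mean log2 CPM, over 35 relabellings of the cultures, the highest other r was 0.575 and the median 0.363. Their covariance was 0.0823 against a highest other value of 0.0395.

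The last comparison asked whether the response to IL-33 differed between the genotypes. Mcpt2 and Mcpt4 responded less in Nbeal2-/- cells, with log2 differences of response of -2.24 (SE 0.17, adjusted p = 5.48e-06) and -1.74 (SE 0.27, adjusted p = 0.0024). Tpsab1 and Ccl9 responded more, with log2 differences of 2.23 (SE 0.27, adjusted p = 0.000351) and 2.57 (SE 0.21, adjusted p = 9.2e-06). Both started lower in untreated Nbeal2-/- cells and stayed below WT with IL-33, Ccl9 at 79.7 ± 12.3 against 123 ± 7.20 CPM and Tpsab1 at 114 ± 3.97 against 263 ± 21.2 CPM (SD, n = 4 each). With IL-33, 17 of 25 cell cycle genes fell and 2 rose in Nbeal2-/- cultures. That list call was lost with an estimated correlation (camera adjusted p = 0.341). In WT cultures 8 rose and 11 fell, with no common direction.

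Here and below, a lower log2 response can be a larger fall or a smaller rise, and a higher one the reverse. Of 25 cell cycle genes 23 had a lower log2 response in Nbeal2-/- and 2 did not pass (25 adjusted over the list alone, camera adjusted p = 2.34e-37, adjusted p = 0.0461 with an estimated correlation). Cdc20 differed by -0.70, Ccnb1 by -0.63, Tyms by -0.54 and Mcm5 by -0.43 on the log2 scale. The mean log2 response of the 25 genes was -0.05 ± 0.11 in WT and -0.58 ± 0.05 in Nbeal2-/- (SD, n = 4 cultures each), a difference of -0.52 with an exact two-sided permutation p of 0.0286, the smallest that 70 arrangements allow. Their mean log2 CPM was 6.52 ± 0.15 in untreated WT, 6.47 ± 0.09 in WT with IL-33, 6.84 ± 0.03 in untreated Nbeal2-/- and 6.26 ± 0.03 in Nbeal2-/- with IL-33.

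**Figure D5:**
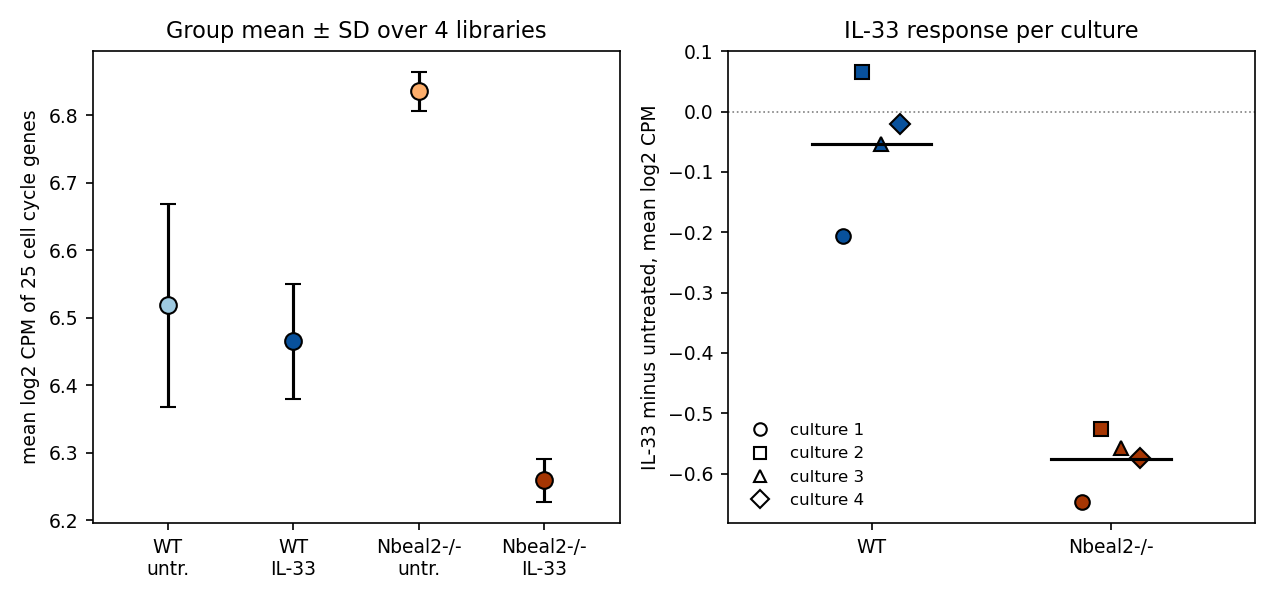
Mean log2 CPM of the 25 cell cycle genes by group, as mean and SD over 4 libraries, and the mean log2 response to IL-33 of each of the 8 cultures. The untreated Nbeal2-/- group is the highest at 6.84, and the responses of all 4 Nbeal2-/- cultures lie below those of the 4 WT cultures.

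The other largest positive differences were Dusp8 (log2 difference 4.19, SE 0.58, adjusted p = 0.000879), with 0.00496 ± 0.00992 CPM in untreated Nbeal2-/- cells, BC049352 (2.30) and Rab11fip5 (1.76). The other largest negative ones under the same limits, which Ccl24 does not meet, were Mcpt8 (-1.36), the early response gene Egr2 (-1.19) and the histone gene H2ac13 (-1.18). Because Dusp8 was near the floor in untreated Nbeal2-/- cells, its fitted difference depends on the prior count. Of 13 chemokine genes 6 had a higher log2 response in Nbeal2-/-, 2 a lower one and 5 did not pass (10 called adjusted over the list alone, camera adjusted p = 0.00133, adjusted p = 0.145 with an estimated correlation). Ccl6 differed by 1.18 and Ccl4 by 0.83, while Ccl24 differed by -2.65. Ccl6 fell with IL-33 in both genotypes, and on the log2 scale it fell less in Nbeal2-/-. Of 25 MAP kinase genes 4 had a lower log2 response and 21 did not pass (7 called adjusted over the list alone, camera adjusted p = 0.000652, adjusted p = 0.294 with an estimated correlation), with Junb at -0.62 and Myc at -0.41. Of 20 glycolysis and hypoxia genes 1 had a higher log2 response, Pfkfb3 at 0.50, and 19 did not pass (3 called adjusted over the list alone, camera adjusted p = 3.67e-05, adjusted p = 0.487 with an estimated correlation). Of 23 granule exocytosis genes 2 had a higher log2 response, Stx11 at 0.40 and Sytl2 at 0.39, and 21 did not pass (3 called adjusted over the list alone, camera adjusted p = 0.0174, adjusted p = 0.163 with an estimated correlation).

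A further 4 lists were called by camera, each of them lost when single libraries were left out. Of 23 NF-kB genes 4 had a higher log2 response, Icam1 at 0.61 and Tnfaip3 at 0.43 among them, 1 a lower one and 18 did not pass (7 called adjusted over the list alone, camera adjusted p = 0.0325, adjusted p = 0.346 with an estimated correlation). It ended without WT IL-33 library 4 (0.0511) or Nbeal2-/- untreated library 4 (0.0629). Of 21 IL-33 receptor pathway genes none passed (0 adjusted over the list alone, camera adjusted p = 0.0325, adjusted p = 0.488 with an estimated correlation). It ended without WT untreated library 2 (0.0643), WT IL-33 library 4 (0.0511), Nbeal2-/- untreated library 1 (0.0804) or Nbeal2-/- IL-33 library 1 (0.0664). Irak3 had a difference of 0.34 with an adjusted p of 0.0874 here and of 0.35 with 0.0424 by DESeq2. Of 20 cholesterol synthesis genes none passed (0 adjusted over the list alone, camera adjusted p = 0.0325, adjusted p = 0.662 with an estimated correlation). It ended without WT untreated library 1 (0.146) or 4 (0.0515), WT IL-33 library 3 (0.151), Nbeal2-/- untreated library 2 (0.117) or 4 (0.103), or Nbeal2-/- IL-33 library 1 (0.285) or 3 (0.0990). Of 6 megakaryocyte and platelet markers 1 had a higher log2 response, Vwf at 0.57, and 5 did not pass (1 adjusted over the list alone, camera adjusted p = 0.0461, adjusted p = 0.346 with an estimated correlation). It ended without WT IL-33 library 2 (0.0750) or 3 (0.129), WT untreated library 4 (0.0560), Nbeal2-/- untreated library 1 (0.0507) or 4 (0.0736), or Nbeal2-/- IL-33 library 1 (0.0888).

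The other 13 lists were not called, with camera adjusted p from 0.0909 to 0.807. Counts of genes with a higher log2 response, with a lower one and tested were 1, 1 and 21 for mast cell identity, 4, 4 and 21 for granule content, 0, 3 and 19 for cytokines, 0, 0 and 16 for BEACH proteins, 0, 0 and 26 for the lysosome, 1, 0 and 13 for eicosanoid synthesis, 0, 1 and 16 for the interferon response and 0, 0 and 18 for the stress response. Markers of monocytes had 0, 1 and 9, of basophils 1, 2 and 10, of lymphocytes and dendritic cells 0, 0 and 7, of progenitors 1, 0 and 10 and of erythroid cells 0, 1 and 8. Adjusted over each list alone, the numbers called were 4, 9, 6, 0, 0, 1, 2 and 2, and for the markers 2, 4, 0, 1 and 1. Tpsb2 differed by 0.89, Serpinb1a by -0.62, Ebi3 by -0.58, Tnf by -0.51, Adgre1 by -0.76 and Tfrc by -0.44. Hspa5 had a difference of -0.25 with an adjusted p of 0.055 here and of -0.24 with 0.0115 by DESeq2. Median, mean and test differed in sign for the granule content, NF-kB, eicosanoid, monocyte, basophil and erythroid lists.

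The response differed in 706 of 15470 genes, 311 with a higher and 395 with a lower log2 value in Nbeal2-/-, and 58 differed over 2-fold (42 higher, 16 lower). Of the 706, 211 moved the same way in both genotypes and more in Nbeal2-/-, and 161 the same way and more in WT. A further 171 were called in Nbeal2-/- alone, 115 in WT alone, and 48 were called in opposite directions. The count rose to 1174 without WT untreated library 1. It was 462 without WT untreated library 2, 439 without WT IL-33 library 4, 442 without Nbeal2-/- IL-33 library 1, 461 without Nbeal2-/- IL-33 library 3 and 462 without Nbeal2-/- untreated library 4. Without the 4 libraries numbered 1, a choice made after seeing the data, it was 1279, and with DESeq2 it was 1207. On simulated counts for this contrast 13.2% of DESeq2 calls were false, against 4.03% with edgeR. That was a single draw from dispersions estimated by edgeR, with most genes unchanged, so it cannot account for the larger DESeq2 count. Of the 22 lists 9 were called, and 1 of those, the cell cycle list, with an estimated correlation.

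The overall size of the response was also compared. The 859 genes that rose over 2-fold with IL-33 on average over both genotypes rose by a mean log2 of 2.21 ± 0.06 in WT and 2.31 ± 0.01 in Nbeal2-/- (SD, n = 4 cultures each), a difference of 0.10 with an exact two-sided permutation p of 0.0286. With any of Nbeal2-/- cultures 1 to 4 left out the difference was 0.0981, 0.106, 0.0989 and 0.0997, each with an exact permutation p of 0.0571. Without the minimum fold it was 0.0147 (exact permutation p = 0.286). The 1099 genes that fell had means of -1.79 ± 0.14 and -1.60 ± 0.06, a difference of 0.19 with an exact two-sided permutation p of 0.0571. Without WT culture 1 that difference was 0.240 (exact permutation p = 0.0286).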

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

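Tests chosen only after the result was seen were the ratios from the fits on 2 groups (the fits with all libraries were planned), leaving out the libraries numbered 1, the Y-linked slope and all tests of the genes near Nbeal2. In 164 groups of 4 libraries, over named genes, total counts and the mitochondrial share, 14 single values lay far from the other 3. For normally distributed values chance alone gives about 1 in 20. A single count beside 3 libraries without any is always flagged, so that rate does not apply to genes near the floor. WT culture 1 had low Nbeal2, at 224 CPM without and 183 CPM with IL-33, and high Nradd with IL-33, at 7.01 CPM. Nbeal2-/- culture 1 had high Cd74, at 1.82 CPM without and 1087 CPM with IL-33, and low Il9 with IL-33, at 85.0 CPM. Other single values were Kit at 1784 CPM in WT IL-33 library 2, Tpsab1 at 4.23 CPM in WT untreated library 4, Mcpt1 at 0.0642 CPM in Nbeal2-/- untreated library 4 and Dusp8 at 0.198 CPM in WT untreated library 3. Single low counts gave Il9 at 0.0178 CPM in WT untreated library 1 and 0.0198 CPM in Nbeal2-/- untreated library 1, Dusp8 at 0.0198 CPM in Nbeal2-/- untreated library 1 and Csf2 at 0.0214 CPM in Nbeal2-/- untreated library 4, where the other libraries of each group held no count.

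Among the genes named for the responses to IL-33 in each genotype, 22 had a response that differed between the genotypes by the interaction test of edgeR. On the log2 scale it was higher in Nbeal2-/- for Tpsab1 (2.23, adjusted p = 0.000351), Cxcl16 (1.65, 0.00244), Ccl5 (1.53, 0.0406), Tgm2 (1.12, 0.00786), Cyp4a12b (1.06, 0.0274), Ccl3 (0.99, 0.00665), Tpsb2 (0.89, 0.0113), Gzmc (0.84, 0.0324), Stx11 (0.40, 0.014) and Cd34 (0.30, 0.014). It was lower for Mcpt2 (-2.24, 5.48e-06), Mcpt4 (-1.74, 0.0024), Egr2 (-1.19, 0.0275), Tk1 (-0.77, 0.00411), Cdc20 (-0.70, 0.0024), Ccnb2 (-0.68, 0.0105), Plk1 (-0.62, 0.00358), Ebi3 (-0.58, 0.007), Tnf (-0.51, 0.00561), Gbp3 (-0.45, 0.0229), Mcm5 (-0.43, 0.00267) and Mcm4 (-0.30, 0.00608). A higher value can be a larger rise or a smaller fall. Tgm2 and Cyp4a12b fell with IL-33 in both genotypes, and on the log2 scale they fell less in Nbeal2-/-.

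The first pattern is that more genes were called between the genotypes without IL-33 than with it, by a ratio of 3.21, and 1.94 over 2-fold. A lower depth with IL-33 is argued against, since with every library thinned to 36405209 counts the ratio was 3.22 (5339 against 1660 genes). Unequal spread under a shared estimate is argued against as the whole source. The median SD of log2 CPM within groups was 0.134 and 0.142 without IL-33 and 0.0929 and 0.0849 with it in WT and Nbeal2-/-. Fitted on its own 2 groups, each comparison gave a ratio of 1.23, and 1.93 over 2-fold. Without the libraries numbered 1 the SDs were 0.0962 and 0.0748 without IL-33 and 0.0860 and 0.0789 with it, and the ratio was 2.92 in 1 fit (5993 against 2051 genes) and 2.67 in fits on 2 groups (5599 against 2096). Smaller genotype differences with IL-33 remain open as a biological hypothesis. Over 5513 genes called for the mean genotype effect the size of the log2 fold was larger without IL-33 for 78.4%, by a median of 0.134. The wider spread without IL-33 also enlarges fold sizes there, and this share was not computed without the libraries numbered 1.

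The second pattern is that cell cycle genes responded to IL-33 with a larger fall in Nbeal2-/- than in WT cultures. The libraries numbered 1, which stand apart, are argued against as its source, since 24 of the 25 genes were called lower without them. A different mix of male and female cells is also argued against, since with a Y-linked covariate that has its own slope with IL-33 the median log2 difference of the 25 genes was -0.529, against -0.541 without it (median SE 0.113), and 20 were called lower. Against spread between cultures alone, the exact two-sided permutation p was 0.0286 for 4 against 4 cultures, the smallest that 70 arrangements allow. It is weak evidence, since this list stood out among 22 in the same cultures and the p is not adjusted for that. A genotype effect stays open as a biological hypothesis whose mechanism was not tested, and so do differences in culture density or age, which the labels do not give.

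The third pattern is that genes near Nbeal2 on chromosome 9 differed between the genotypes. Reads running on from Nbeal2 in proportion to its level are argued against. They would lower Nradd, 337 bp away, in Nbeal2-/-, where it was higher (7.91 against 5.97 CPM without and 14.4 against 4.83 CPM with IL-33). A further 4 genes 1 to 5 Mb away were called the same way in both conditions with a change over 0.5. They cannot decide this, since genes far from Nbeal2 changed so too, at 2.69%. A chromosome segment from another strain stays open, since 4.44% of 135 tested genes within 5 Mb changed so against 2.69% elsewhere (Fisher's exact two-sided p = 0.184). Of 15079 windows of that reach around tested genes, 16.9% held as high a share. Those windows overlap each other and include ones near Nbeal2. Nbeal2-/- cells mixed into WT culture 1 are argued against, since over 1134 genes away from Nbeal2 that culture lay at a median of 0.108 of the way to Nbeal2-/- without and -0.13 with IL-33, against 0.607 and 0.383 for Nbeal2. A knockout copy of the segment in that culture stays open. Both its libraries lay over 0.25 of the way at 3 of 13 called genes within 5 Mb (23.1%) and at 5.73% of the others (Fisher's exact two-sided p = 0.0371, and 0.149 by Holm's method over the 4 WT cultures). The median of the 13 lay at 0.22 without and 0.0649 with IL-33, where 1 copy would put genes that depend on it about half-way.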

How the results depend on the processing

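Leaving out the 4 libraries numbered 1, also in fits on 2 groups, the Y-linked covariate and the BEACH list without Nbeal2 were tests chosen only after the result was seen. No list called by camera, no named gene (with RLE factors, DESeq2 or the replicate block) and no difference in the size of the response reversed its direction under the alternatives run for it. Lists that were not called did. The counts of called genes stayed within 1.5 times the reported ones with RLE and upper-quartile factors, no filter, a stricter filter, limma-voom, limma on log2(RPM + 1) and the replicate block, in all 5 comparisons. Apart from single libraries left out, they did not in 3 cases: for the difference of the responses DESeq2 called 1207 genes and the libraries without number 1 gave 1279, against 706, and for the genotypes with IL-33 the fit on 2 groups called 3113, against 1730. Without number 1 the other counts were 9376 for IL-33 in WT, 8607 for IL-33 in Nbeal2-/-, 5993 for the genotypes without IL-33 and 2051 with it, and 5599 and 2096 in fits on 2 groups. With the Y-linked covariate they were 5491 and 1635 for the genotypes without and with IL-33 and 685 for the difference of the responses, from which a covariate alike in both libraries of a culture nearly cancels. With its own slope with IL-33 it gave 556.

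With the replicate block the counts were 9107 for IL-33 in WT, 8693 for IL-33 in Nbeal2-/- and 932 for the difference of the responses. In these comparisons, where the numbers pair the libraries, the block changed the call of Nbeal2 and of the glycolysis list for IL-33 in Nbeal2-/-, and no other call of a named gene or list. Across the genotypes number 1 matched and numbers 2 to 4 did not, with correlations of 0.75, 0.22, -0.09 and 0.13 without IL-33 and 0.52, -0.32, 0.09 and 0.06 with it, and that block gave 5938 and 2032 genes. It gave adjusted p of 0.0319 for the glycolysis list and 0.0481 for the progenitor list with IL-33, neither called otherwise. Lists not called with or without the block turned direction with it in 9 cases. With their adjusted p under the block these were cell cycle (0.902) and monocyte markers (0.993) for IL-33 in WT, BEACH proteins (0.901) and monocyte markers (0.923) for IL-33 in Nbeal2-/-, basophil (0.989) and progenitor markers (0.989) without IL-33, NF-kB genes (0.986) and lymphocyte markers (0.960) with IL-33, and monocyte markers (0.808) for the difference of the responses.

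The numbers of lists called by camera fell with an estimated correlation to 5 and 4 for IL-33 in WT and in Nbeal2-/-, 2 and 3 for the genotypes without and with IL-33 and 1 for the difference of the responses, from 8, 9, 12, 8 and 9. Fry, which does not compare a list with other genes, called 18 for IL-33 in each genotype, and 16, 9 and 7 for the others. Without Nbeal2 itself the BEACH list lost its call for the genotypes without IL-33 (adjusted p = 0.149), since the deleted gene carried part of it. Without number 1 the cholesterol list lost its call for the difference of the responses (adjusted p = 0.0865). Lists not called turned direction with fry in 2 cases, eicosanoid synthesis without IL-33 (0.857) and NF-kB genes with it (0.966). Without number 1 they did in 8: mast cell identity for IL-33 in WT (0.904), the IL-33 receptor pathway (0.881) and BEACH proteins (0.881) for IL-33 in Nbeal2-/-, monocyte (0.777) and basophil markers (0.651) without IL-33, the IL-33 receptor pathway (0.954) and cholesterol synthesis (0.713) with it, and granule content for the difference of the responses (0.969). For lists not called, directions were not compared with single libraries left out. The numbers of lists called without number 1 were 8, 9, 13, 9 and 11 in the same order. The cause was not tested for the other changes. All 239 values of named genes kept their call with RLE factors and 236 did with DESeq2, where Nbeal2 for IL-33 in Nbeal2-/- and Irak3 and Hspa5 for the difference of the responses gained it. DESeq2 also made more false calls on simulated counts (10% to 13.4% of calls against 3.11% to 6.49%). Those counts were drawn from dispersions estimated by edgeR, so they cannot account for these gains. Depth limits genes with few counts in a group, such as Il9 in untreated cells, whose ratio of 20879 in WT has a counting interval from 3747 to 824701.

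Leaving out each library gave 8338 to 9494 genes for IL-33 in WT, 7897 to 8808 in Nbeal2-/-, 4268 to 6336 for the genotypes without IL-33, 1171 to 2393 with it and 439 to 1174 for the difference of the responses. The last went beyond 1.5 times the reported count for 6 libraries: 1174 without WT untreated library 1, 462 without WT untreated library 2, 439 without WT IL-33 library 4, 442 and 461 without Nbeal2-/- IL-33 libraries 1 and 3 and 462 without Nbeal2-/- untreated library 4. The numbers of lists were 8 to 8, 9 to 10, 11 to 14, 7 to 9 and 6 to 11. Leaving out cultures, the difference in the size of the response was 0.0835 to 0.12 for risen genes and 0.133 to 0.240 for fallen genes, and 0.0147 for risen genes without a minimum fold.

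Other splits of the same libraries into groups of 4, 35 in each case, bear on chance. Only the real split, 1 of 35, gave as many genes in each comparison, and no smaller share is possible. For the genotypes and the difference of the responses that share is under 0.05, though number 1 matched across the genotypes. For IL-33 in each genotype the libraries pair by culture, so free splits cannot exclude chance there. For IL-33 in WT and in Nbeal2-/- and for the genotypes with IL-33 the counts were 8903, 8524 and 1730 against at most 2, 0 and 0 in the others. Splits that mix the groups carry the real effect in their spread, so low counts are expected there. For the genotypes without IL-33 the count was 5549 against a highest of 2882, from the split that swaps WT untreated library 1 with Nbeal2-/- untreated library 2. The response differed in 932 genes in the blocked fit and in 0 under every other split. For the number of lists chance cannot be excluded where 6, 3, 3 and 4 of 35 splits gave as many in the first 4 comparisons, with 8, 9, 12 and 8 called and 8, 9, 14 and 9 at most in other splits. For the difference of the responses 1 of 35 did, with 9 against at most 6. Where cultures pair, the 7 other splits that part all pairs called 0 genes in each genotype, but so few splits cannot reach a share under 0.05.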

Other observations

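The tests on genes near Nbeal2 were chosen only after the result was seen. Cells of both genotypes carried transcripts on the lists of platelet and basophil markers. Gp1ba, a platelet adhesion receptor gene, stood at 251 ± 14.4 CPM in untreated WT and 223 ± 20.7 CPM in untreated Nbeal2-/- (SD, n = 4 each), and Vwf at 198 ± 24.1 and 109 ± 13.4 CPM. Cd69, an activation marker gene on the basophil list, stood at 884 ± 32.0 CPM in WT and 983 ± 99.6 CPM in Nbeal2-/- with IL-33.

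Glb1, the beta-galactosidase gene 3746915 bp from Nbeal2 and chosen after its values were seen, had log2 fold changes of -1.14 without (adjusted p = 1.11e-06) and -0.95 with IL-33 (adjusted p = 2.2e-05).

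The count of 23.1% of called genes near Nbeal2 that lie between the genotypes in WT culture 1 includes Glb1 and 3000002C10Rik, a transcribed processed pseudogene. Glb1 lay between the genotypes in WT culture 4 too, at 0.318 of the way without and 0.273 with IL-33. WT cultures 2, 3 and 4 gave 0, 2 and 1 of 13, with Fisher's exact p of 1, 1 and 0.356. Within 1, 2, 5, 10 and 20 Mb of Nbeal2, the shares of genes called the same way in both conditions with a change over 0.5 were 10%, 5.71%, 4.44%, 4.46% and 4.88%. Fisher's exact p was 0.101, 0.245, 0.184, 0.124 and 0.0397, and the last was 0.199 when adjusted for 5 windows by Holm's method.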
